A study of Mus musculus with 18 samples.

How the data were processed

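The series holds 18 RNA sequencing libraries in 6 groups of 3: memory Th2 cells with high ST2 cultured with IL-2 alone or with IL-2 and IL-33, eosinophils labelled without or with amphiregulin, and lungs of OVA-treated wild-type and dGATA mice. The labels give BALB/c mice, total RNA taken with TRIzol and a stranded mRNA library kit. Samples were grouped by their titles and label fields alone. The study's design text speaks of house dust mite, whereas the lung labels say OVA, and the labels do not spell out what dGATA stands for. They also do not say whether replicates came from separate animals, cultures or donors, so the p-values measure only the spread between these samples.

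The deposited files hold FPKM values per gene, which the authors made with Cufflinks 2.0.2 from TopHat 1.3.2 and Bowtie 0.12.8 alignments to mm10, according to the submitters' processing notes. Reads were not analysed here, and the files hold no read counts, so count models were not used. The Th2 and lung tables hold 23746 entries for 23284 mouse gene symbols, of which 240 have several entries, and these were summed per symbol. The eosinophil tables hold 25593 entries for 25548 symbols, 45 with several, and their symbols and coordinates are human: the last gene on chromosome 1 ends at 249213345, against 195176715 in the mouse tables. They were analysed as human tables, and no human genome was used. Starts in the mouse tables were raised by 1, after which 56.2% of 20479 symbols had the same start as the RefSeq annotation of GRCm38, against 3.4% before. Of the human symbols, 114 of Y-linked and X-inactivation genes were left out of every test and gene table.

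Total depth is not given in the sources used here. Relative depth was estimated from the most frequent ratio of low FPKM values, below 0.2 FPKM, between each library and the first of its comparison, in bins of 0.01 log2 units. In the order of the replicate numbers it was 1.0, 1.34, 1.03, 1.24, 0.67 and 0.74 for Th2 libraries 1 to 6, 1.0, 0.56 and 0.44 for eosinophils without amphiregulin and 0.81, 0.71 and 0.36 with it, and 1.0, 0.67 and 0.63 for wild-type and 0.65, 0.76 and 0.58 for dGATA lungs. Of 10 housekeeping genes, 0 values were at 0, with a lowest FPKM of 9.82 in mouse and 8.09 in human libraries. Small RNA features took 19.99 to 38.39% of all FPKM in the eosinophil libraries, 12.08 to 21.36% in the Th2 cells and 4.0 to 5.12% in the lung.

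Each comparison used its own 6 libraries. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were kept, values were transformed to log2(FPKM + 1) without further scaling, and limma 3.58.1 in R 4.3.3 was fitted with the trend option. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called higher or lower. Focus genes below the filter were compared by an exact permutation of the 6 libraries, except EGFR and ERBB3 in the eosinophils, which were not tested. Gene lists with at least 5 tested members were tested by camera in limma with a preset correlation of 0.01, adjusted over the lists of each comparison. Beside it stand the number of members called over all genes, the number called after adjusting over the list alone, and camera with an estimated correlation. Groups, comparisons, tests, lists and most alternatives were fixed before the data were examined. Matching of mouse list symbols to human symbols was made after the files had been seen.

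Genes were named by a rule. It covers the focus genes of each comparison whatever their result, the 8 genes with the largest log2 difference in each direction among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM, and up to 4 members with the smallest p of each list described. Clone, predicted and locus names were counted but not named. Genes outside the rule are said to be so where they are named. Some genes the rule covers are not reported here.

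Sample numbers recur in both groups of the eosinophil and lung comparisons. After removing the group means, eosinophil libraries of equal number correlated at 0.399, 0.356 and 0.670, above the threshold of 0.1, although numbers 2 and 3 also correlated with each other at 0.281 and 0.308. The fit with the number as a block is therefore given beside the planned fit. Lung libraries of equal number correlated at -0.286, -0.116 and -0.243 and were not treated as pairs. No number recurs between the Th2 groups, but Th2 libraries 5 and 6 correlated at 0.314, and 3 and 2 at 0.267. Libraries 5 and 6 correlated negatively with the remaining libraries of the other group. Removing the group means forces such negative values on average, so they are no separate evidence. Libraries 5 and 6 also had the lowest relative depth, 0.67 and 0.74, and their titles spell ST2 high differently. A batch shared by libraries 5 and 6 is therefore possible, and no block was fitted in the Th2 cells.

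The alternatives were other pseudocounts, no filter or a stricter filter, rescaling to a common sum (TPM), median-of-ratios scaling, quantile normalization, limma without the trend, robust variance moderation, array weights, the replicate block, leaving out each library, a model over several comparisons, leaving out small RNA features, and other list tests. The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 log2 units. It recovered 78% and 96% of them with the Th2 libraries (5 false calls among 10296 genes), 0% and 38% with the eosinophil libraries (3 of 12636) and 64% and 90% with the lung libraries (10 of 13727).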

Results

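RNA levels were measured in 18 libraries forming 6 groups of 3. Memory T helper 2 (Th2) cells with high surface ST2, the IL-33 receptor, had been cultured for 3 days with IL-2 alone (n = 3) or with IL-2 and IL-33 (n = 3). Eosinophils were labelled without amphiregulin (n = 3) or with it (n = 3), and whole lung of OVA-treated mice was wild type (n = 3) or dGATA (n = 3). Values were in FPKM, and genes were tested with limma on log2(FPKM + 1), a scale that understates differences of genes near or below 1 FPKM. Depth, relative to the first library of each comparison, ran from 0.67 to 1.34 in the Th2 cells, from 0.36 to 1.0 in the eosinophils and from 0.58 to 1.0 in the lung. The eosinophil tables list human genes, although the labels name mouse, and they are read here as human. Their genome build is not given in the sources used here.

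In the first comparison the question was which genes of memory Th2 cells respond to IL-33. Il1rl1, which encodes ST2 itself, rose 9.95-fold, from 51.5 ± 6.73 to 512 ± 6.10 FPKM (n = 3 per group, log2 difference 3.30, SE 0.108, adjusted p = 7.09e-06, limma, chr1:40439649-40465414, mm10). Areg, the gene of the growth factor amphiregulin, rose 8.52-fold, from 92.9 ± 16.7 to 792 ± 298 FPKM (log2 3.03, SE 0.259, adjusted p = 0.000261, limma, chr5:91139615-91148432). Il5, an eosinophil growth and survival cytokine, rose 6.06-fold to 1563 ± 302 FPKM (log2 2.58, SE 0.146, adjusted p = 4.38e-05, limma, chr11:53720794-53725103). Spp1, which encodes osteopontin, fell 5.96-fold in the same T cells, from 764 ± 47.9 to 128 ± 2.52 FPKM (log2 -2.57, SE 0.0857, adjusted p = 7.46e-06, limma, chr5:104435111-104441053). Il4 moved less, to 5677 ± 1759.9 from 3255 ± 366 FPKM (log2 0.76, adjusted p = 0.0398, limma), a call lost with no filter (0.172), quantile normalization (0.0642) or array weights (0.0509) and on leaving out any library but IL-33 replicate 4 (highest 0.102). Il13 did not pass (5754 ± 843 and 8741 ± 2658 FPKM, adjusted p = 0.102, limma). Gata3, the lineage-defining transcription factor of Th2 cells, rose 2.16-fold (adjusted p = 0.00279, limma), as did the IL-2 receptor chain gene Il2ra by 2.21-fold (adjusted p = 0.00445, limma). Egfr, a receptor for amphiregulin, lay below the expression filter, at 0.176 ± 0.113 and 1.17 ± 0.185 FPKM (n = 3 per group, exact permutation p = 0.1, the smallest that 3 against 3 can give).

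Of the 8 largest rises, all but Ctla4 were of genes with a mean below 6 FPKM under IL-2 alone. The decoy IL-1 receptor gene Il1r2 went from 2.64 ± 1.67 to 302 ± 63.7 FPKM (log2 6.48, adjusted p = 4.13e-05, limma). The CD30 gene Tnfrsf8 went from 1.91 ± 1.31 to 123 ± 6.04 FPKM (log2 5.54). The inhibitory receptor gene Ctla4 rose from 44.6 ± 34.7 to 1253 ± 62.6 FPKM (log2 5.44, SE 0.900, adjusted p = 0.00384, limma). Its 3 IL-2 libraries were unequal, at 64.4, 65.0 and 4.54 FPKM. Sval1 (log2 7.30), the neuropeptide precursor gene Nts (6.12), the parathyroid hormone gene Pth (5.35, or 4.34 without IL-2 replicate 5, listed at 0), the matrix metalloproteinase gene Mmp10 (5.24) and Stfa2 (4.92) completed the 8 largest. Of the 8 largest falls, 4 were of genes on the interferon response list. Oasl2 fell from 45.8 ± 4.33 to 0.496 ± 0.0566 FPKM (log2 -4.97, SE 0.0977, adjusted p = 2.85e-06, limma), and Rsad2 from 60.1 ± 7.13 to 1.03 ± 0.233 FPKM (log2 -4.91). Ifit3 (-4.83) and Ifit2 (-4.55) were also on that list. The membrane protein genes Ms4a4c and Ms4a4b, the interferon-induced gene H28 and Ifi202b were the others, not on it (log2 -4.80, -4.72, -4.52 and -4.48).

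**Figure D1:**
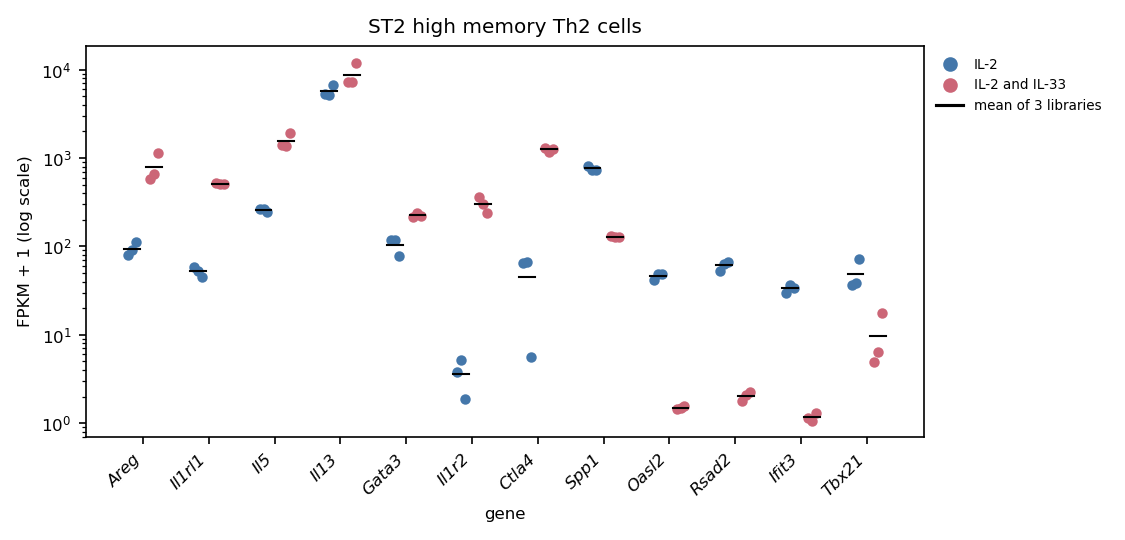
Expression (FPKM + 1, log scale) of 12 genes in memory Th2 cells cultured with IL-2 (blue) or with IL-2 and IL-33 (red); each point is a library and each black bar the mean of 3 libraries. Areg, Il1rl1 and Il5 lie higher with IL-33, while Spp1 (log2 -2.57) and the interferon response genes Oasl2, Rsad2 and Ifit3 lie lower.

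Among gene lists written before the values were examined, the interferon response list moved furthest. All 16 of its 16 tested genes fell, counted over all genes or adjusted over the list alone. Their median log2 difference was -3.60 (list adjusted p = 2.14e-11, limma camera; adjusted p = 0.414 with an estimated correlation). Of 9 Th2 cytokine genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.0293, limma camera; adjusted p = 0.487 with an estimated correlation). Il10, an anti-inflammatory cytokine gene, led them, from 217 ± 152 to 2860.0 ± 325 FPKM (log2 4.16, or 3.22 without IL-2 replicate 5, which stood at 42.5 FPKM). Il9 fell from 478 ± 141 to 129.7 ± 95.6 FPKM (log2 -2.07). Of 13 Th2 identity genes, 8 rose and none fell by either adjustment (list adjusted p = 0.000461, limma camera; adjusted p = 0.414 with an estimated correlation). Among them were the chemokine receptor gene Ccr8 (log2 2.49) and the lipid-sensing nuclear receptor gene Pparg (1.74). Of 17 glycolysis genes, 7 rose and none fell by either adjustment (list adjusted p = 0.0119, limma camera; adjusted p = 0.501 with an estimated correlation). They included the lactate exporter gene Slc16a3 (log2 1.95) and the glucose transporter gene Slc2a3 (1.31). Of 11 T cell marker genes, 8 rose and 2 fell by either adjustment (adjusted p = 0.00180, limma camera; adjusted p = 0.414 with an estimated correlation). Cd3g (log2 1.35) and Cd3d (1.42) of the T cell receptor complex were among those that rose.

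Of 9 Th1 genes, 5 fell and 1 rose (2 rose and 5 fell adjusted over the list alone), but the list as a whole did not pass (adjusted p = 0.169, limma camera). Tbx21, the Th1 master regulator gene T-bet, named after values were seen, fell from 47.8 to 8.62 FPKM (log2 -2.50, adjusted p = 0.00730, limma), and the chemokine receptor gene Cxcr3 from 15.3 ± 10.2 to 1.24 ± 0.750 FPKM (log2 -2.74). Of 8 fibrosis factors, 5 fell and 1 rose (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.0853, limma camera). The metalloproteinase inhibitor gene Timp1 fell (log2 -1.80; not called in the model over the 12 mouse libraries, adjusted p = 0.0796, limma) and the vascular growth factor gene Vegfa rose (1.31), at a mean of 6.13 ± 1.09 FPKM.

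Of 10296 tested genes, 1680 were higher and 2651 lower with IL-33 (4331 genes, 42.1%). By at least 1 log2 unit 514 were higher and 419 lower, and 5314 genes had unadjusted p below 0.05. The 3 values of the groups did not overlap for 56.7% of tested genes, against 10% by chance. The median gene stood at log2 -0.106 as deposited and at -0.002 under median-of-ratios scaling. Which direction held more calls depended on this: higher genes made up 38.8% as deposited, 54.4% after rescaling to a common sum (TPM) and 53.5% under median-of-ratios. Leaving out IL-33 replicate 2 or 4 lowered the count of lower genes to 1633 or 1530. All list calls were lost once the correlation among members was estimated. With fry, a list test that does not set members against the other genes, 11 of 19 lists were called. The 5 lists called by camera were among them.

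In the second comparison the question was what amphiregulin changes in eosinophils, and whether it raises SPP1. SPP1, which encodes the matrix-binding cytokine osteopontin, was not higher: it averaged 3127 ± 2610.2 FPKM without amphiregulin and 179 ± 163 with it (n = 3 per group, log2 -3.72, SE 1.54, adjusted p = 0.999, limma, chr4:88896802-88904563 in the files' coordinates). Values under equal sample numbers were 4158 and 164, 5064 and 349.9, and 159 and 24.3 FPKM, lower in 3 of 3 pairs. In the alternative fit with the sample number as a block SPP1 fell (block SE 0.365, adjusted p = 0.00871, limma). FCER2, the gene of the low-affinity IgE receptor CD23, rose from 0.375 ± 0.362 to 336 ± 215 FPKM (log2 7.63, SE 0.659, adjusted p = 0.0225, limma, with the block 0.00197, chr19:7753643-7767032). ADAMTSL4, encoding an extracellular matrix glycoprotein, rose 6.78-fold to 45.9 ± 9.93 FPKM (log2 2.58, SE 0.243, adjusted p = 0.0293, limma). The sodium pump subunit gene ATP1B2 (0.0739 ± 0.128 to 15.3 ± 8.16 FPKM, log2 3.80) and the apolipoprotein L gene APOL4 (0.440 ± 0.299 to 11.1 ± 3.90 FPKM, log2 3.03) completed the 4 genes that rose. No transcript other than small RNA features was among the 22 features called lower.

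EGFR was listed at 0 in all 6 libraries. The related receptor genes ERBB2 (0.840 ± 0.106 and 0.776 ± 0.354 FPKM, n = 3, exact permutation p = 0.9) and ERBB3 (0.470 ± 0.485 and 0.210 ± 0.245 FPKM) lay below the filter, as did AREG (0.495 ± 0.546 and 0.504 ± 0.395 FPKM, exact permutation p = 1). The eosinophil genes did not pass, with or without the block. The eotaxin receptor gene CCR3 averaged 87.4 ± 43.6 and 53.6 ± 32.4 FPKM and the lectin gene SIGLEC8 41.5 ± 29.8 and 32.4 ± 18.4 (n = 3). The IL-5 receptor gene IL5RA averaged 6.67 ± 3.42 and 2.70 ± 1.83, and the eosinophil peroxidase gene EPX 0.668 ± 0.733 and 8.81 ± 12.8 FPKM (n = 3). IL1RL1 averaged 18.9 ± 9.77 and 14.1 ± 7.96 FPKM, and the profibrotic cytokine gene TGFB1 155 ± 43.4 and 175 ± 15.6 FPKM (n = 3).

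Because the libraries differed strongly between sample numbers, the fit with the number as a block called more: 67 genes higher and 74 lower, of which 51 were not small RNA features. These counts depended on the pairs, at 7 and 12 without pair 3 and 422 and 261 without pair 4. The naming rule was applied to this fit after the data had been seen. The chemokine gene CCL22 went from 11.6 ± 8.93 to 1284 ± 1054 FPKM (log2 6.13, block SE 0.369, adjusted p = 0.00118, limma). The transglutaminase gene TGM2 went from 7.20 ± 6.21 to 306 ± 254 (log2 5.14), and the mannose receptor gene MRC1 from 1.82 ± 1.15 to 55.3 ± 38.5 (log2 4.11). The macrophage elastase gene MMP12 (log2 6.41), the lectin gene CD209 (4.27) and the glutamyltransferase gene GGT5 (3.26) also rose. The chemokine gene CCL13 went from listed at 0 in 3 libraries to 9.97, 77.4 and 10.5 FPKM. Lower in the block fit, besides SPP1, were the lysosomal protease gene LGMN (148 ± 86.5 to 6.98 ± 5.91 FPKM, log2 -4.29, adjusted p = 0.000269, limma) and the gelatinase gene MMP9 (log2 -4.08). The endotoxin co-receptor gene CD14 fell too (160.3 ± 127 to 8.07 ± 6.31 FPKM, log2 -3.82), with the haemoglobin scavenger receptor gene CD163 (-2.91).

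**Figure D2:**
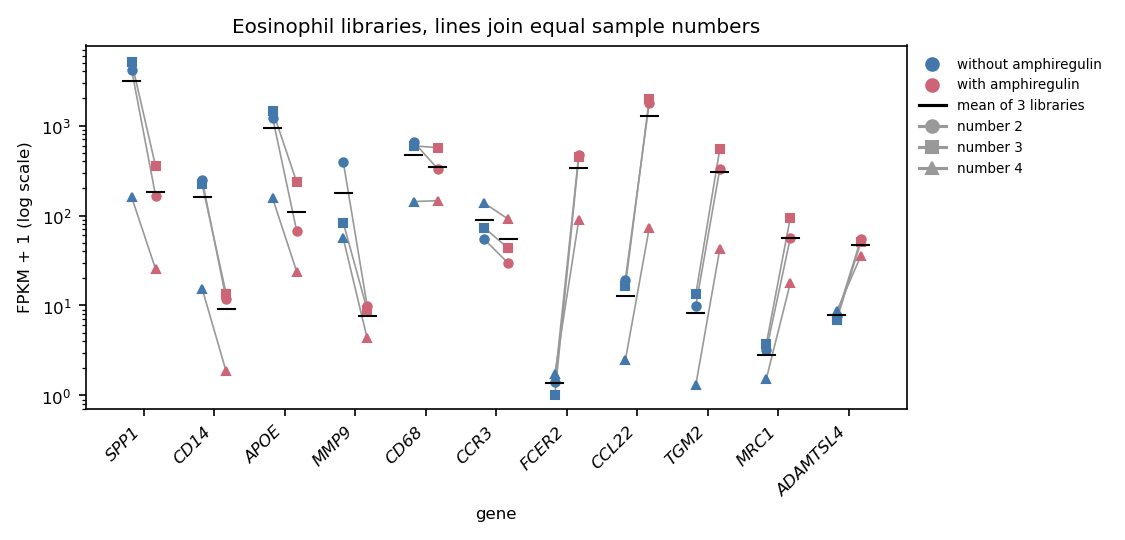
Expression (FPKM + 1, log scale) of 11 genes in libraries labelled without (blue) and with (red) amphiregulin; marker shapes and grey lines join equal sample numbers, and black bars are means of 3 libraries. SPP1 (log2 -3.72), CD14 and APOE lie lower with amphiregulin in each pair, while FCER2, CCL22, TGM2 and MRC1 lie higher.

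Among the gene lists, the alternative activation list was higher (7 tested; adjusted p = 0.000418, limma camera; adjusted p = 0.601 with an estimated correlation). None of its genes passed over all genes, 4 rose and 1 fell adjusted over the list alone, and with the block MRC1, CCL22, CCL24 and CLEC10A, the last named after values were seen, rose and CD163 fell. The block call (adjusted p = 0.000523, limma camera) was also lost, with adjusted p = 0.415 with an estimated correlation. Several cell-type lists also moved, which bears on cell purity. Without amphiregulin the macrophage genes APOE (939.8 ± 692 FPKM), LYZ (901 ± 617) and CD14 and the T cell gene CD3E (88.6 ± 33.1) averaged as much as or more than CCR3 (87.4 ± 43.6, n = 3). T cell markers were lower in 12 of 12 genes (adjusted p = 3.26e-05, limma camera), macrophage markers in 10 of 12 (0.00516; 7 of 12 after rescaling to TPM) and neutrophil markers in 7 of 9 (0.0228). Dendritic cell markers were higher in 6 of 6 genes (adjusted p = 9.26e-06, limma camera), and plasma cell markers in 5 of 5 (0.0414). Cell cycle genes were higher in 24 of 27 (adjusted p = 0.0223, limma camera), glycolysis genes in 13 of 17 (0.01) and oxidative phosphorylation genes in 19 of 22 (0.00151). None of these 8 lists had a gene that passed over all genes, 2 dendritic genes and 0 of the others rose or fell adjusted over the list alone, and each lost its call with an estimated correlation (adjusted p = 0.601 or higher). With the block, 3 macrophage genes (CD14, APOE and MERTK) and 1 neutrophil gene (CAMP) fell and 1 dendritic gene (CD209) rose over all genes. Adjusted over the list alone with the block, 10 T cell genes were lower, 4 neutrophil genes lower and 2 higher, 4 macrophage genes lower and 1 higher, and 5 dendritic genes higher. Mast cell and basophil genes (7 of 7 below 0, adjusted p = 0.127, limma camera) were called lower with the block only (0.000285; adjusted p = 0.415 with an estimated correlation), 2 of them adjusted over the list alone.

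The fibrosis factor list did not pass (16 tested, 0 over all genes, 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.163, limma camera), and its median turned from log2 -0.15 as deposited to 0.0215 after rescaling to TPM. With the block it passed at adjusted p = 0.0300 (limma camera), with MMP12 higher and SPP1, MMP9, MMP14 and MMP2 lower, and had adjusted p = 0.426 with an estimated correlation. The eosinophil marker list did not pass either (6 tested, 0 called, adjusted p = 0.852, limma camera; with the block 0.530). Adjusted over the list alone with the block, 1 of its genes was higher and 2 were lower.

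Of 12636 tested genes, 4 were higher and 22 lower, all 22 being small RNA features and 16 of those copies of 5S RNA with identical values. Unadjusted p was below 0.05 for 393 genes, and groups did not overlap for 6.7% of genes. The 10% expected by chance holds for libraries without pairs, and differences between sample numbers reduce such separation here. The higher share was 15.4% as deposited and 26.7% after rescaling to TPM, which moved the median gene from log2 0.0167 to 0.209. On simulated data from these libraries a log2 change of 1 was recovered for 0% of genes and a change of 2 for 38%, so genes that did not pass are weak evidence of no change. Without the small RNA features the call on FCER2, ADAMTSL4, ATP1B2 and APOL4 was lost, with 0 genes higher and 0 lower, although their log2 differences did not change. With the block and without small RNA features, all 4 were called. Leaving out with-amphiregulin library 4 gave 48 and 24, and leaving out any other library 0 to 1 and 4 to 6.

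In the third comparison the question was what dGATA, labelled a knockout, changes in the lung of OVA-treated mice. Gata1, the erythroid and eosinophil transcription factor gene, was 1.65, 1.23 and 0.963 FPKM in wild-type lungs and 0.126, 0.134 and 0.314 in dGATA lungs (1.28 ± 0.344 and 0.191 ± 0.106, n = 3, below the filter, exact permutation p = 0.1, the smallest possible, chrX:7959260-7967815, mm10). Of 5 tested eosinophil markers, 2 fell. Ccr3, the eotaxin receptor gene, fell from 5.36 ± 0.733 to 0.125 ± 0.111 FPKM (log2 -2.50, SE 0.135, adjusted p = 0.00326, limma, chr9:124021971-124031689). Prg2, which encodes eosinophil major basic protein, fell from 9.70 ± 3.27 to 0.428 ± 0.311 FPKM (log2 -2.88, SE 0.285, adjusted p = 0.0427, limma, chr2:84980461-84983632). Cebpe, a granulocyte transcription factor gene outside the naming rule and chosen after values were seen, also fell (4.18 ± 1.31 FPKM in wild type, log2 -2.23, adjusted p = 0.0271, limma). Epx, the eosinophil peroxidase gene, was 0.262, 0.388 and 0.228 FPKM in wild type and listed at 0 in all 3 dGATA lungs (n = 3, exact permutation p = 0.1). Siglec5, the older symbol of Siglecf, averaged 7.81 ± 0.704 and 6.09 ± 1.39 FPKM without passing.

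Genes that are not on the eosinophil marker list changed as well. Tmem72, a transmembrane protein gene, was 10.7, 11.5 and 10.8 FPKM in wild type and listed at 0 in all 3 dGATA lungs (log2 -3.59, SE 0.0872, adjusted p = 8.49e-05, limma). Arl2bp, encoding a binding partner of the small GTPase ARL2, fell from 62.2 ± 5.12 to 18.4 ± 2.31 FPKM (log2 -1.71), and the heat shock co-chaperone gene Dnajb1 from 45.4 ± 3.51 to 22.1 ± 1.27 FPKM (log2 -1.01). Ubtd1, encoding a ubiquitin-like domain protein, rose from 0.871 ± 0.206 to 12.5 ± 3.46 FPKM (log2 2.82, SE 0.210, adjusted p = 0.0104, limma). Glo1, which detoxifies methylglyoxal, rose from 28.9 ± 1.61 to 65.7 ± 3.96 FPKM (log2 1.16, SE 0.0850, adjusted p = 0.0104, limma, chr17:30592862-30612659). The CTP synthase gene Ctps2 (log2 1.25, adjusted p = 0.00815, limma) and the Ras-like gene Rasd1 (log2 1.17, adjusted p = 0.0427, limma) rose too.

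Genes of fibrosis and of the type 2 response did not pass. Spp1 averaged 58.7 ± 8.98 FPKM in wild type and 171 ± 219 in dGATA lungs, where the 3 libraries held 36.6, 423 and 52.3 (adjusted p = 0.933, limma). The collagen gene Col1a1 averaged 116 ± 21.1 and 74.6 ± 28.3 FPKM (log2 -0.69, adjusted p = 0.751, limma). Col3a1 averaged 215 ± 28.8 and 152 ± 67.7, and the fibronectin gene Fn1 179.9 ± 12.7 and 153 ± 92.8 FPKM (n = 3). Areg (2.05 ± 0.537 and 2.18 ± 0.737 FPKM), Il33 (57.3 ± 6.54 and 62.0 ± 27.8), Gata2 (32.6 ± 3.69 and 48.4 ± 14.0) and Gata3 (3.59 ± 0.397 and 3.16 ± 0.426) did not pass. Il5 (exact permutation p = 0.6) and Il13 (exact permutation p = 1) lay below the filter (n = 3).

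**Figure D3:**
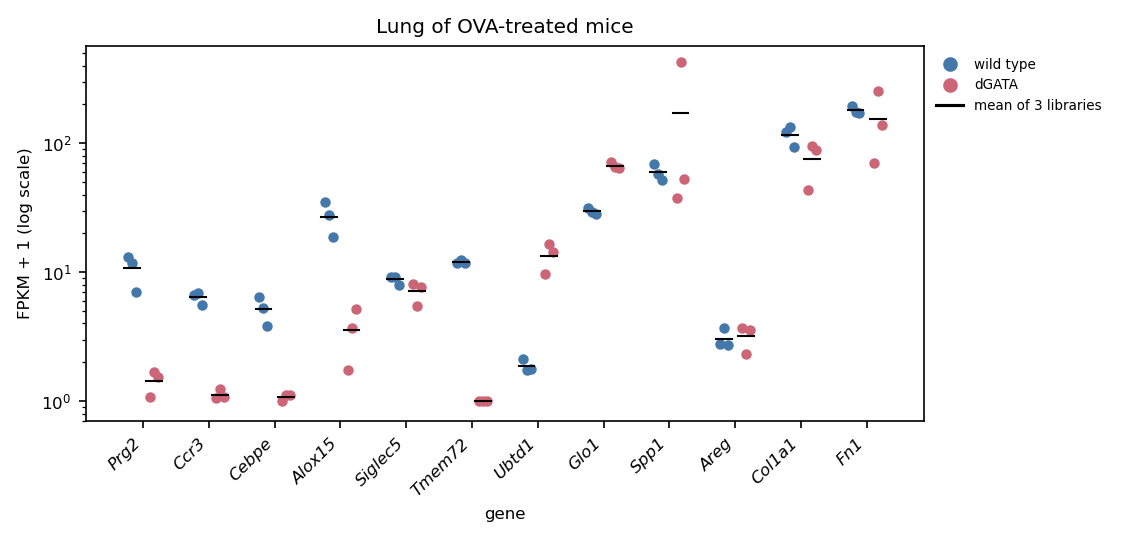
Expression (FPKM + 1, log scale) of 12 genes in lungs of OVA-treated wild-type (blue) and dGATA (red) mice; each point is a library and each black bar the mean of 3 libraries. Prg2, Ccr3 (log2 -2.50), Cebpe and Tmem72 lie near 0 in dGATA lungs, Ubtd1 and Glo1 lie higher, and the 3 dGATA values of Spp1 spread from 36.6 to 423 FPKM.

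Among the gene lists, eosinophil markers were lower (5 tested, 2 fell over all genes and 3 adjusted over the list alone, adjusted p = 5.46e-07, limma camera; adjusted p = 0.832 with an estimated correlation). Of 22 collagen and matrix genes, 19 had log2 differences below 0 and the list was lower, with 0 genes passing over all genes or adjusted over the list alone (adjusted p = 0.00304, limma camera; adjusted p = 0.835 with an estimated correlation). Without dGATA library 1 the collagen and matrix call was lost (0.0660). Lower values were not particular to matrix genes. Smooth muscle markers lay below 0 in 7 of 7 (median log2 -0.35, adjusted p = 0.0772, limma camera) and fibroblast markers in 6 of 9 (-0.26, 0.0848). Cardiac muscle markers lay below 0 in 7 of 8 (0.289), whereas endothelial markers lay above 0 in 7 of 9 (0.153). None of these lists was called. Mast cell and basophil genes were below 0 in 8 of 9, with 0 passing by either adjustment (adjusted p = 0.0228, limma camera; adjusted p = 0.866 with an estimated correlation), and lost their call after rescaling to TPM (0.105). Surfactant-producing alveolar type 2 cell genes were higher in 9 of 9 (adjusted p = 0.000532, limma camera; adjusted p = 0.835 with an estimated correlation) and ciliated cell genes in 6 of 8 (0.0228; adjusted p = 0.866 with an estimated correlation). Each had 0 genes passing by either adjustment, and each call was lost under quantile normalization (0.129 and 0.138). Oxidative phosphorylation genes were higher in 21 of 22 as deposited, with 0 passing by either adjustment (adjusted p = 0.000333, limma camera; adjusted p = 0.866 with an estimated correlation). They were higher in 11 of 22 after rescaling to TPM, where the median turned to -0.00313. Erythroid markers lay above 0 in 4 of 4 tested genes (median log2 1.88), with 0 passing by either adjustment and too few for a list test. The fibrosis factor list (21 tested, 0 passing; adjusted p = 0.226, limma camera) and the alternative activation list (12 tested, 0 passing; 0.596) did not pass.

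Some genes of the alternative activation and eosinophil chemokine lists, singled out after values were seen, spread widely among the dGATA lungs. The chitinase-like gene Chi3l3 was 166, 6620.1 and 3322 FPKM in dGATA libraries 1, 2 and 3 and 3409 ± 546 in wild type, and the resistin-like gene Retnla 656, 25231 and 10859 against 10334 ± 1436. The chemokine gene Ccl8 was 18.7, 1399.8 and 673 FPKM against 717 ± 107, and the eotaxin gene Ccl11 4.64, 97.1 and 31.2 against 68.6 ± 10.4 (n = 3). None of the 4 passed. In all 4 genes dGATA library 1 was the lowest of the dGATA lungs and library 2 the highest, as also for Spp1. The spread was thus one between lungs and shared by these genes. With 1 dGATA lung far below wild type, the lack of a call for these genes is weak evidence of no change.

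Of 13727 tested genes, 6 were higher and 7 lower, including 2 and 1 small RNA features. Unadjusted p was below 0.05 for 939 genes, and groups did not overlap for 14.1% of genes, against 10% by chance. Leaving out dGATA library 3 left 1 higher and 1 lower, and leaving out wild-type libraries 1, 2 and 3 gave 3, 2 and 2 higher and 3, 3 and 5 lower. Of the 9 named genes that passed, 7 kept their call under every other filter, scaling and weighting that tested them, Prg2 and Rasd1 being the exceptions. Only 1, Tmem72, also kept it without each library in turn.

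The last question was whether the genes that differed with amphiregulin in the human eosinophil libraries also moved in the dGATA lung. Because only 4 genes were called higher, the higher set held the 50 with the largest moderated t without the block, and 39 matched a tested mouse gene. Their median log2 difference in the lung was -0.03, and limma camera did not call the set. The 22 features called lower were all small RNA, and 0 matched. The 100 genes with the largest moderated t in each direction had medians of -0.09 (71 higher genes tested) and -0.07 (41 lower genes tested) and were not called either. Nor were the genes called with the block, small RNA features left out, a choice made after the data were seen (42 higher genes tested, median -0.14, and 32 lower genes, median -0.12). The lack of a call is weak evidence of no shared change. On simulated data from the eosinophil libraries a log2 change of 1 was recovered for 0% of genes. In whole lung the eosinophil gene Epx lay below the filter.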

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

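Several alternatives were chosen after the results had been seen: leaving out small RNA features, the block without small RNA features or without a pair, the model over the 12 mouse libraries, array weights estimated gene by gene, the block with an estimated correlation, and lung sets from the block. The planned model over all 18 libraries was not run because the eosinophil tables are human. A count-based alternative was not run because the files hold no counts. The lower eosinophil set had no value in the lung. Unless stated, the cause of a difference was not tested.

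In Th2 cells, against 1680 genes higher and 2651 lower, rescaling to TPM gave 1586 lower and array weights 4050 lower. Leaving out each library gave 1210 to 1727 higher and 1530 to 3135 lower. Of 19 lists, 5 were called, 4 to 6 without each library, 0 with an estimated correlation and 11 with fry. Of the 55 named genes called, 49 kept their call under every setting that tested them and 52 without each library.

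In eosinophils, against 4 genes higher and 22 lower, a pseudocount of 0.1 gave 1 higher and 6 lower, no filter 2 higher, the stricter filter 2 higher and 6 lower, TPM 8 higher and quantile normalization 1 higher and 6 lower. Array weights gave 1875 higher and 1361 lower without converging, and gene by gene 104 and 62. With small RNA features left out the counts were 0 and 0. Leaving out each library gave 0 to 48 higher and 4 to 24 lower, and none of the 4 named genes called kept its call throughout.

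With the replicate block the eosinophil counts were 67 higher and 74 lower, and 119 and 77 with small RNA features left out too. With the block and a pair left out they were 117 and 101 (number 2), 7 and 12 (number 3), and 422 and 261 (number 4). Of 22 lists, 9 were called, 5 to 9 without each library (5 without the library labelled without amphiregulin, number 4), 14 with the block, 14 with the block and small RNA features left out, 13, 6 and 11 with the block and pair 2, 3 or 4 left out, 0 with an estimated correlation, 0 with fry and 0 with the block and an estimated correlation.

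In the lung, against 6 genes higher and 7 lower, the stricter filter gave 4 lower, array weights 558 higher and 878 lower without converging, and gene by gene 11 and 11. The model over the 12 mouse libraries gave 19 and 77. Leaving out each library gave 1 to 7 higher and 1 to 9 lower. Of 39 lists, 6 were called, 8 to 20 without each library (20, 10 and 11 without dGATA library 2, dGATA library 1 and wild-type library 3), 0 with an estimated correlation and 1 with fry, the eosinophil markers. With the replicate block, whose numbers do not pair here, 2 genes were higher and 1 lower, and 8 lists were called.

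The 100 genes with the largest moderated t in eosinophils, taken in place of the 50 higher genes and the called lower features, left the lung result without a call, as did the genes called with the replicate block.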

Other observations

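The explanations weighed below, and the tests of them, were chosen after the results were seen; the comparison with other groupings of the libraries was written before. The report leaves out several lists. With IL-33, 7 of 16 T cell activation receptor genes rose and 4 fell, by either adjustment (adjusted p = 0.102, limma camera), with the costimulatory gene Tnfrsf9 up from 60.0 ± 6.26 to 489 ± 71.8 FPKM and the checkpoint gene Pdcd1 down from 73.8 ± 10.6 to 21.1 ± 5.99 (n = 3). Of 8 regulatory T cell genes, 4 rose and 2 fell by either adjustment (adjusted p = 0.169, limma camera). Of 18 NF-kB targets, 2 rose and 6 fell by either adjustment (adjusted p = 0.534, limma camera), although Tnfaip3, a feedback inhibitor of that pathway, rose (log2 1.21). Of 22 oxidative phosphorylation genes, 1 rose and 8 fell, or 1 and 7 adjusted over the list alone (adjusted p = 0.0774, limma camera). Gzma, a granzyme gene named after values were seen, rose from 35.5 ± 16.8 to 582 ± 252 FPKM (log2 4.01, adjusted p = 0.00104, limma).

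In the eosinophil libraries the immediate early list did not pass (18 tested, 0 by either adjustment, adjusted p = 0.222, limma camera). With the block it was higher (adjusted p = 0.0439, limma camera, 2 higher adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), and EGR2 alone rose over all genes (18.1 ± 11.5 to 59.5 ± 36.1 FPKM, adjusted p = 0.00871, limma). The inflammatory cytokine list did not pass (12 tested, 0 over all genes, 1 lower adjusted over the list alone, adjusted p = 0.246, limma camera). With the block it was higher (adjusted p = 0.00355, limma camera, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), and the IL-1 receptor antagonist gene IL1RN rose and CXCL3 fell over all genes. In the lung 6 of 6 eosinophil ribonuclease genes lay below 0 with 0 passing (adjusted p = 0.191, limma camera), and 15 stress response genes held 1 that fell, Dnajb1 (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.0538, limma camera). Alox15, a lipoxygenase gene of eosinophils and macrophages, averaged 26.0 ± 7.98 and 2.55 ± 1.74 FPKM without passing (n = 3, adjusted p = 0.175, limma).

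The number of called genes was compared with that of the other ways to split the same libraries, and in each case only 1 split, the real one, reached its count. The real count was 4331 against at most 4 in Th2 cells and 13 against at most 3 in the lung (10 splits each). In eosinophils it was 26 against at most 5 (10 splits), and with the block 141 against at most 3 (4 splits that part every pair). These are too few splits for a share under 0.05. Every other split also mixes the groups compared, so a real difference would widen its spread and lower its count. The counts of the other splits therefore do not measure how many calls arise without a difference.

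The eosinophil libraries labelled with amphiregulin had less SPP1, CD14 and APOE and more FCER2, CCL22 and MRC1 than those labelled without. Of 12 macrophage list genes, 9 had a paired 95% interval above -2.01, the median of the paired lower genes. This argues against a loss of macrophages of that size in the amphiregulin samples. A smaller loss is left open, since 10 of 12 macrophage genes lay below 0. The paired lower genes had also been selected for their fall. A different share of FPKM taken by small RNA features is argued against by its size. The shares, 19.99 to 38.39%, were too alike for a shift of -2.01. Rescaling without these features left the median of the paired lower genes at -2.01. Exchanged group labels cannot be told apart from a true response. With the block the immediate early list was higher at adjusted p = 0.0439 in limma camera, but at 0.426 with an estimated correlation, under which 0 of 22 lists passed. Its direction could not decide this in any case: the labels give 3 days of culture, and EGFR was listed at 0. A response of myeloid cells in the samples is left open.

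In the dGATA lung 4 named genes rose and 3 fell that are not eosinophil markers. A chromosome segment carried along with the Gata1 allele is argued against by position: the nearest called gene on X lay 154.9 Mb away, and 1 of 13 called genes was on X. Loss of eosinophils, for the genes that were higher, cannot be told apart from an effect of the allele: their lowest log2 difference was 1.16, but only genes past the threshold entered, and indirect effects were not tested, nor was this explanation for the genes that fell. A different strain background of the 2 lung groups cannot be told apart from an effect of the allele: 3 genes were at 0 in all libraries of 1 group and at 5 FPKM or more in all of the other, and the highest other split also had 3. Without small RNA features it was 1, Tmem72, against 0.

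Interferon response genes fell together in Th2 cells given IL-33. Scaling of the libraries is argued against, since the median log2 difference nearest to 0 under 3 other scalings was -3.50. Loss of a large share of B cells, macrophages, neutrophils, mast cells or dendritic cells in the IL-33 cultures is argued against. Of their 56 markers, 3 reached 5 FPKM in IL-2 alone. This cannot exclude a small number of such cells that act on the T cells, which is left open. All 3 tested macrophage markers lay below 0 with IL-33, 2 of them called lower. Of 4 tested dendritic cell markers, 1 rose and 1 fell. Natural killer and cytotoxic cells were not covered and are left open: 3 of 5 such genes fell and 1 rose by either adjustment (adjusted p = 0.507, limma camera). Less interferon beta made in the IL-33 cultures is a candidate explanation: Ifnb1 fell from 4.37 ± 0.356 to 0.0687 ± 0.0597 FPKM (log2 -2.33, adjusted p = 2.27e-05, limma). The labels give a single culture time of 3 days. Whether Ifnb1 fell before the list genes or as a consequence of their fall therefore cannot be told.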
